A study of Mus musculus with 12 samples.

How the data were processed

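RNA sequencing was carried out on LSK cells, the lineage-negative bone marrow fraction that is positive for Sca-1 and Kit and holds the blood stem cells, and on cells labelled MPP (multipotent progenitor), from wild-type (WT), Tet2 knockout (KO) and Tet2 mutant (Mut) mice of a mixed 129/C57/B6 background. Per the labels, each genotype's cells came from the pooled marrow of 2 mice aged 10 weeks, and each pool gave 2 technical replicate libraries per population. The 12 libraries thus form 6 groups of 2. The labels name the second population MPP in the descriptions and Lin in the titles, and MPP is used here. They do not give the residues altered in Mut or the sorting gates of MPP.

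Per the labels, RNA was amplified and barcoded, ERCC spike-in RNAs of known composition were added, and 150 bp read pairs were sequenced on a NextSeq 500. Reads were trimmed with Trim Galore 0.4.1 and mapped to the mm10 mouse genome with TopHat2 2.0.13 at its default parameters. HTSeq 0.6.1 and Cufflinks are named without their role, and the strand setting and the gene annotation are not given. The deposited tables hold raw counts per gene symbol, one table per population, with 24630 symbols each, of which 92 are spike-ins and 24538 are genes. The values are whole numbers whose column totals differ, and no scaling had been applied to them. All 12 columns were used. The column titled as a second copy of library 3 in the MPP table was assigned to MPP KO replicate 2, the only library of the labels without a column of its own.

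Gene counts were compared with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group (minimum count 10, minimum total count 15), libraries were scaled by TMM over the genes, and quasi-likelihood models with a mean per group were fitted. The 6 libraries of a population shared the estimate of the spread in the genotype comparisons (13170 genes in LSK, 12947 in MPP, 3 residual degrees of freedom each). A model of all 12 libraries (14033 genes, 6 residual degrees of freedom) served for the differences of a genotype effect between populations, called interactions here and coded as the effect in LSK minus the effect in MPP, and for LSK against MPP in WT. P values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in a comparison. A gene was called at an adjusted p below 0.05. The replicates are technical libraries of a single pool of mice per genotype, so every p value and error measures the spread between libraries of a pool and not between mice. Gene counts per library ran from 9181027 to 23532847, so that a count of 0 in a library leaves up to 0.327 to 0.127 CPM open (floor of 3 counts). CPM were computed on the TMM-scaled library size and are shown as mean ± SD of the 2 libraries of a group.

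A fold against a group with 0 counts in both libraries was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts in the lower group, the ratio of counts is given with its exact 95% Poisson interval. Reads without molecular identifiers are not independent molecules, so such intervals and floors cover counting error only. Gene positions are from the GENCODE annotation of GRCm38 (release M21), which matched 13754 of the 14033 symbols tested.

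The genes named were chosen by a rule: for KO or Mut against WT, up to 8 higher and 8 lower called genes with the largest fitted changes, whose libraries do not overlap between the groups and whose higher group averages at least 100 counts. For KO against Mut, the interactions and LSK against MPP, up to 5 in each direction were taken, the interactions without the overlap criterion. Predicted genes, clones, small RNAs, immunoglobulin and T cell receptor segments, spike-ins and mitochondrial genes were passed over. Up to 4 called members of each list described, and Tet1, Tet2 and Tet3, were added. Genes were classed as shared when called for KO and for Mut against WT, as KO-distinct when called for KO against WT and for KO against Mut, and as Mut-distinct when called for Mut against WT and for KO against Mut. Groups, comparisons, lists, the naming rule and the alternatives below, unless stated, were fixed before the data were examined.

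A total of 29 gene lists were fixed for the cell types, lineages and pathways that these fractions could hold: blood stem cell (HSC), lymphoid-primed progenitor, granulocyte-monocyte progenitor, megakaryocyte-erythroid progenitor, neutrophil, erythroblast, B cell, T and NK cell, macrophage, mast cell and basophil, stroma and endothelium, dendritic cell and MHC class II, interferon response, inflammatory cytokine and NF-kB, immediate early, cell cycle, cell cycle inhibitor, DNA methylation machinery, TET partner and chromatin, Hox and Meis, p53 target, glycolysis, ribosomal protein, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, replication-dependent histone, sex-linked, Tet2 neighbour and 129-B6 passenger. The mitochondrially encoded list had 0 genes in the tables and the sex-linked list was read per library, which left 27 lists to test. Lists were tested against all other genes with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison), which gave the call, and with an estimated correlation between genes beside it. The fry test, which asks whether a list's genes move on balance in a single direction, was run as well. Members past the threshold are counted over all genes tested and adjusted over the list alone.

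Alternatives tried were DESeq2 size factors (RLE), the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, a test against a 1.5-fold change (glmTreat), scaling by the spike-in counts, the spread shared over all 12 libraries or over only the 2 groups compared, and leaving out each library in turn. In the last case the lone library of a group is assumed to vary like the other groups. Replicate numbers carried no shared deviation (correlations between -0.0297 and 0.0186 across genes). An alternative without Rn45s and Lars2 was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

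The tests were checked on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold. The dispersions were the trend fitted to these libraries, equal for genes of equal abundance and for all groups. For LSK KO against WT, 13 and 53 of these were recovered, with 2 false calls. For MPP KO against WT, 31 and 62 were recovered, with 5 false calls, and for the interaction of KO against WT, 4 and 37, with 5 false calls. Signs were wrong in 0 recovered genes. Among simulated genes above 50 CPM the recovered shares at 4-fold were 92.1%, 100% and 78.4%. In LSK and in MPP a list shifted 2-fold was found and 0 of the unshifted lists were called. The overlap that shared WT libraries alone give between the KO and Mut comparisons was simulated 20 times in each population. These simulations used a trend of dispersion for WT and another for KO and Mut, and so leave out spread particular to single genes.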

Results

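The series compared gene expression in mouse blood stem and progenitor cells labelled Tet2 knockout with cells labelled Tet2 mutant. Tet2 is a dioxygenase of methylated cytosine, and the title of the series places the question in the functions of Tet2 outside catalysis. LSK and MPP cells were sorted from marrow of WT, KO and Mut mice, with 2 technical replicate libraries in each of the 6 groups and 12 libraries in all. Gene counts ranged from 9181027 in LSK WT replicate 1 to 23532847 in MPP Mut replicate 1. A count of 0 in a library allows up to 0.127 to 0.327 CPM. Each genotype was a single pool of mice, so the comparisons below hold for these pools.

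The LSK WT libraries stood apart from the others in several measures. They held 12470 and 12614 detected genes, against 13333 to 14264 in the other 10 libraries, and their 2 libraries correlated across genes at r = 0.744, against 0.879 to 0.917 within the other groups. In 169 genes (1.60% of those with a mean of at least 50 counts), one LSK WT library had 0 counts. Rn45s, the precursor of the ribosomal RNAs, took 3.67% ± 0.0354 of gene counts in LSK WT, 2.49% ± 0.0292 in LSK KO and 1.04% ± 0.0802 in LSK Mut (SD, n = 2), and between 0.937% and 1.06% in the MPP groups. Lars2, the mitochondrial leucyl-tRNA synthetase, took 1.83% ± 0.0947, 1.28% ± 0.0115 and 0.459% ± 0.0241 in the same order, falling together with Rn45s. In MPP WT, KO and Mut it took 0.225%, 0.175% and 0.343%, where it did not follow Rn45s. Whether the counts of Lars2 come from its own mRNA was not tested. Spike-ins took 0.0822% to 0.229% of counts in the LSK libraries, 3.35% ± 0.259 in MPP WT, 3.32% ± 0.188 in MPP KO and 5.02% ± 0.185 in MPP Mut. The proportions among the spike-ins differed as well. ERCC-00130 took 18.6% of spike-in counts in LSK WT and 17.2% in MPP WT, against 2.67% to 3.75% in the KO and Mut groups. In the comparisons with WT below, spike-in totals may thus not be comparable, and shifts under spike-in scaling do not show a change in total expression.

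**Figure D1:**
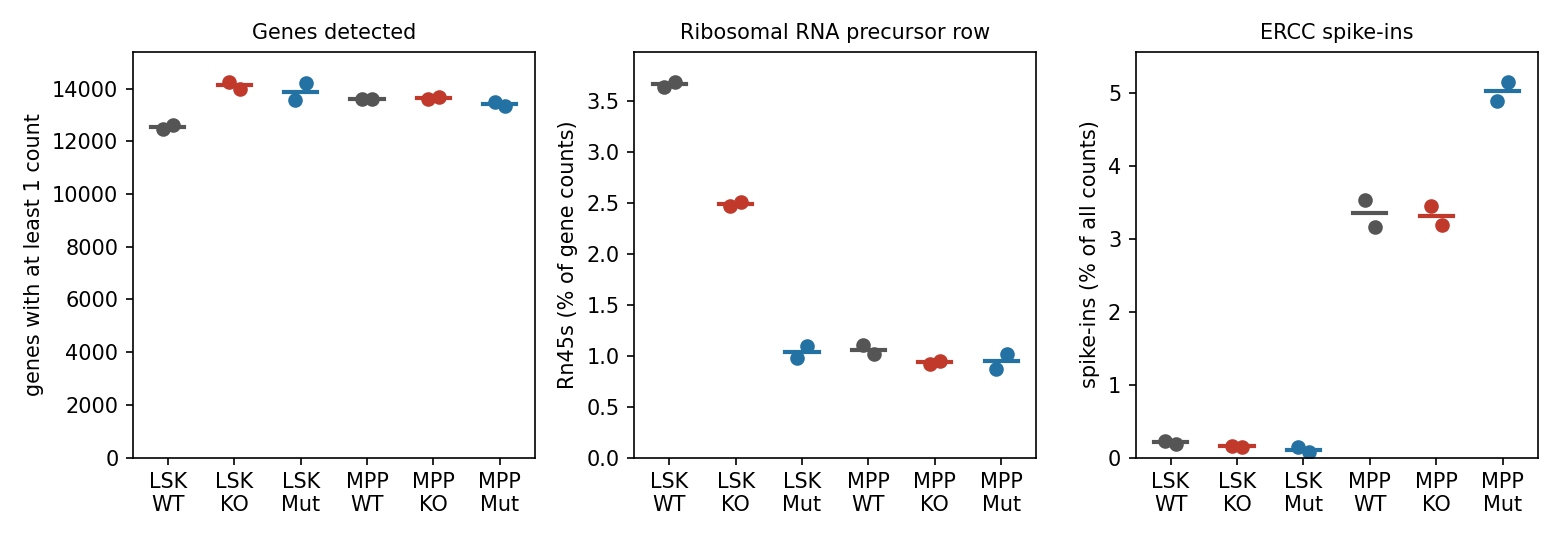
Detected genes (number), Rn45s (percent of gene counts) and spike-ins (percent of all counts) in each library, with points for libraries and bars for group means. LSK WT has the fewest detected genes (12470 and 12614) and the highest Rn45s share (3.67%), and spike-ins are highest in MPP Mut (5.02%).

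Tet2 (chromosome 3, 133463679 to 133545139 of GRCm38, minus strand) was measured first, because the libraries are named by its genotype. In LSK cells its level was 92.6 and 67.1 CPM in the WT libraries (79.8 ± 18.0), 32.0 ± 2.19 in KO and 46.2 ± 0.683 in Mut (SD, n = 2). The difference of KO from WT was -1.32 (log2, SE 0.308) and missed the threshold over all genes (adjusted p = 0.207, unadjusted p = 0.0033), as did that of Mut from WT (-0.79, SE 0.305, adjusted p = 0.221) and that of KO from Mut (-0.53, SE 0.304, adjusted p = 1). In the MPP cells Tet2 was at 32.8 ± 7.07 CPM in WT, 33.0 ± 0.00377 in the libraries labelled MPP KO and 36.7 ± 1.82 in Mut. The log2 difference of the libraries labelled MPP KO from WT was 0.01 (SE 0.268, adjusted p = 0.999). That of Mut was 0.16 (SE 0.267, adjusted p = 0.920), and that of KO from Mut -0.15 (SE 0.267, adjusted p = 0.924). A count of reads over the gene can stay level where a targeted allele still makes a transcript, and the tables hold no values by exon. The KO effect on Tet2 differed between LSK and MPP by -1.31 (SE 0.402, adjusted p = 0.198), and the Mut effect by -0.94 (SE 0.401, adjusted p = 0.266). Tet1 and Tet3, the related dioxygenases, passed no threshold in any of the 6 genotype comparisons. None of these Tet2 differences passed the threshold, and those of KO and Mut from WT in MPP, both near 0, changed sign without MPP WT replicate 2.

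**Figure D2:**
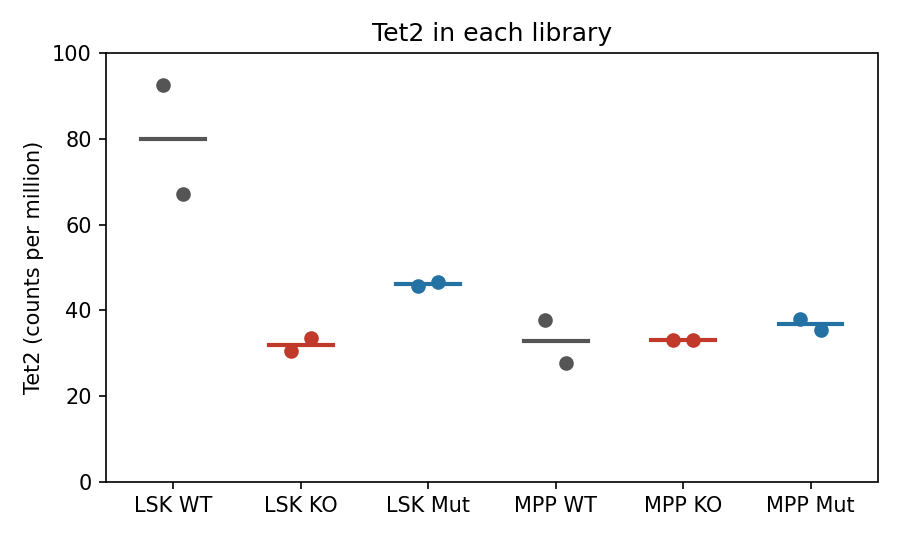
Tet2 level (CPM, vertical axis from 0) in each library of the 6 groups, with points for libraries and bars for group means. The LSK WT libraries lie at 92.6 and 67.1 CPM, the LSK KO mean at 32.0 CPM and the MPP KO mean at 33.0 CPM, beside 32.8 CPM in MPP WT.

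LSK KO against WT compares the libraries labelled KO with WT in the fraction that holds the stem cells, with the reservation that the lower Tet2 count missed the threshold (adjusted p = 0.207). Prg2 and Mpo were higher in KO. Prg2 (chromosome 2, 84980461 to 84983632), which encodes the major basic protein of eosinophil granules, was at 148.0 ± 3.79 CPM in KO. It had 2 counts in WT, all in replicate 2, a ratio of counts of 1532 (95% interval 424 to 12652, adjusted p = 0.00496). Mpo (chromosome 11, 87793581 to 87804413), the myeloperoxidase of neutrophil granules, was 2.44-fold higher (4111 ± 94.6 against 1684 ± 98.4 CPM, adjusted p = 0.00244). Jchain (chromosome 5, 88519809 to 88527891), the joining chain of polymeric immunoglobulins, was 9.36-fold lower (10.5 ± 1.60 against 98.3 ± 7.58 CPM, adjusted p = 0.00798). Rn45s was 1.53-fold lower (log2 -0.61, SE 0.0482, adjusted p = 0.00967), Lars2 1.48-fold lower (log2 -0.57, SE 0.0533, adjusted p = 0.0256), and Pisd-ps1, a pseudogene, 2.72-fold lower (log2 -1.44, SE 0.146, adjusted p = 0.0358). These were all 6 genes called of 13170 tested (2 higher and 4 lower), while 1811 had an unadjusted p below 0.05, against 658 by chance. Leaving out a WT library raised the count of genes to 1475 (without replicate 1) or 1690 (without replicate 2). Leaving out KO replicate 1 or 2 gave 0 calls with edgeR (698 and 762 at an unadjusted p below 0.05), while DESeq2 on all libraries gave 593. Of the 6 genes, 0 kept their edgeR call without each library.

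A total of 11 lists were called for LSK KO against WT, and 0 of them held with an estimated correlation (lowest adjusted p = 0.27 with an estimated correlation). By fry, 5 of the 11 passed in the same direction, and the granulocyte-monocyte, megakaryocyte-erythroid, dendritic, DNA methylation, ribosomal protein and oxidative phosphorylation lists did not. The granulocyte-monocyte progenitor list was higher (camera adjusted p = 0.000164): of its 20 members, Mpo rose over all genes, and 6 rose and 1 fell adjusted over the list alone. The interferon response list was higher (adjusted p = 0.000594, 0 of 34 members over all genes, 2 higher adjusted over the list alone), and so were glycolysis (adjusted p = 0.0121, 2 of 18 members adjusted over the list alone), T and NK cell (adjusted p = 0.000126, 1 of 11), macrophage (adjusted p = 0.0341, 0 of 13), dendritic cell and MHC class II (adjusted p = 0.0121, 0 of 15) and oxidative phosphorylation (adjusted p = 0.00967, 0 of 79). The immediate early list was lower (adjusted p = 1.96e-07), with 0 of 24 members called over all genes and 12 lower adjusted over the list alone. Megakaryocyte-erythroid progenitor (adjusted p = 0.0121, 0 of 20), DNA methylation machinery (adjusted p = 0.00967, 3 lower and 1 higher of 18) and ribosomal protein (adjusted p = 0.00032, 1 lower of 78) were lower, the member counts again adjusted over the list alone. Adjusted p values with an estimated correlation ran from 0.27 for the T and NK, interferon and immediate early lists to 0.514 for oxidative phosphorylation. The interferon, immediate early and ribosomal protein lists kept their calls without each of the 6 libraries. Without WT replicate 1 the granulocyte-monocyte, macrophage, dendritic, glycolysis and oxidative phosphorylation lists lost theirs. Without WT replicate 2 this held for the megakaryocyte-erythroid, T and NK, macrophage, DNA methylation and glycolysis lists, and without KO replicate 1 for the macrophage, dendritic and oxidative phosphorylation lists. Spike-in scaling moved the median of all genes by 0.51 and gave 71 calls, 66 higher and 5 lower.

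LSK Mut against WT compares the libraries labelled Mut with WT in the same fraction. Rn45s, Lars2 and Rplp1 were lower and Mpo was higher in Mut. Rplp1, a protein of the ribosomal stalk, was 4.76-fold lower (390 ± 43.0 against 1860 ± 76.5 CPM, adjusted p = 0.000405), Lars2 4.19-fold lower (log2 -2.07, SE 0.0552, adjusted p = 7.52e-06) and Rn45s lower by a log2 difference of -1.90 (SE 0.0497, adjusted p = 7.52e-06). The ribosomal protein list was lower (median log2 -0.59, camera adjusted p = 2.79e-13, but 0.34 with an estimated correlation), with 13 of 78 members lower and 0 higher over all genes, and 27 lower and 3 higher adjusted over the list alone. Rps21 (3.49-fold), Rps24 (2.24-fold) and Rps9 (2.15-fold) were among those that fell. In the granulocyte-monocyte progenitor list (adjusted p = 3.67e-07, but 0.34 with an estimated correlation), Mpo rose 2.81-fold, Elane, neutrophil elastase, 3.09-fold and Ly6c2, a monocyte surface protein, 11.2-fold, and 10 of 20 members rose and 1 fell adjusted over the list alone. Immediate early genes were lower as a list (adjusted p = 3.04e-05, but 0.34 with an estimated correlation), with Klf4 4.13-fold, Nr4a1 2.95-fold and Fosb 2.10-fold lower and 6 of 24 members lower adjusted over the list alone. Per1, a circadian repressor, fell 3.90-fold (adjusted p = 0.0225), Rapgef2 5.64-fold (adjusted p = 0.0388), Fyco1 4.06-fold (adjusted p = 0.0392), and the transporters Slc16a11 9.86-fold (adjusted p = 0.0465) and Slc26a11 7.77-fold (adjusted p = 0.0388).

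Of the 10 lists called for LSK Mut against WT, 0 held with an estimated correlation (adjusted p = 0.34 to 0.346 with an estimated correlation), and 7 passed fry in the same direction, without the T and NK, DNA methylation and TET partner lists. The others were higher for dendritic cell and MHC class II (adjusted p = 0.00125, with Cd74 2.67-fold and H2-Ab1 3.07-fold higher, 5 of 15 adjusted over the list alone), for cell cycle (adjusted p = 0.00286, with the mitotic kinase Aurkb 3.14-fold and the replication helicase subunit Mcm2 1.94-fold higher, 7 higher and 1 lower of 36 adjusted over the list alone) and for glycolysis (adjusted p = 0.00286, with Ldha 1.42-fold higher, 8 higher and 1 lower of 18 adjusted over the list alone). Higher too were T and NK cell (adjusted p = 0.0343, with Nkg7 1.66-fold higher, 1 of 11) and interferon response (adjusted p = 0.0438, with Ifi47 2.57-fold higher, 4 of 34). The DNA methylation machinery list was lower (adjusted p = 0.0343, 4 lower and 1 higher of 18 adjusted over the list alone), although its only member called over all genes, the isocitrate dehydrogenase Idh2, was 1.78-fold higher. The TET partner and chromatin list was lower (adjusted p = 0.0438), with the histone methyltransferase Kmt2a 2.53-fold lower. Genes with 0 counts in WT were led by Ehd3, an endosomal recycling protein (at least 206-fold higher, with 1035 counts in Mut, adjusted p = 0.0225), Arhgef11 (at least 118-fold, adjusted p = 0.0313) and Tcaf1 (at least 86.6-fold, adjusted p = 0.0392). These bounds cover counting error only. In LSK WT, 169 genes with a mean of at least 50 counts had 0 counts in one library, a spread that the bounds leave out. Prg2 had 310 counts in Mut and 2 in WT, a ratio of 92.5 (95% interval 25.4 to 768, adjusted p = 0.0152). Ifi209 was 94.6-fold, Snx7 50.8-fold, Oip5 19.6-fold and Disp1 16.1-fold higher.

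In all, 168 genes were called for LSK Mut against WT, 71 higher and 97 lower, with 2518 at an unadjusted p below 0.05 and 658 by chance. Without LSK WT replicate 1 or 2 the count was 2430 or 2631, without LSK KO replicate 1 or 2 it was 11 in each case, and without LSK Mut replicate 1 or 2 it was 5 or 6. Of the 16 genes named by fold, 2 kept their call without each of the 6 libraries, Rplp1 and Lars2. The ribosomal protein, granulocyte-monocyte, immediate early and glycolysis lists kept theirs without each library, while the interferon list lost its call without any of them. The T and NK list lost its call without WT replicate 1, WT replicate 2 or Mut replicate 2, the dendritic list without WT replicate 1, the cell cycle and DNA methylation lists without WT replicate 2, and the TET partner list without any library but Mut replicate 1. DESeq2 gave 1398 genes and a 1.5-fold threshold 19. A spread from only the 2 groups compared gave 5 genes, and of the 16 genes named by fold only Rplp1 and Lars2 kept their call there. The shared spread joins WT libraries with the less variable KO and Mut libraries, so p values against WT in LSK may be too small. Spike-in scaling moved the median of all genes by 1.10 and gave 3002 calls, 99.3% of them higher, with Rplp1 still lower past the threshold and Lars2 and Klf4 not past it. The LSK Mut libraries differed in their spike-in share (0.139% and 0.0822% of counts), and spike-in proportions differed between WT and Mut, so this shift does not show a change common to all genes.

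LSK KO against Mut compares the libraries labelled KO with those labelled Mut, whose Tet2 counts did not differ past the threshold. Ribosomal RNA was higher and Jchain lower in KO than in Mut. Lars2 was 2.83-fold higher (adjusted p = 9.81e-05), Rn45s 2.44-fold (log2 1.29, SE 0.0488, adjusted p = 9.81e-05), Rplp1 2.43-fold (947 ± 87.6 against 390 ± 43.0 CPM, adjusted p = 0.0186) and Prg2 16.5-fold (148.0 ± 3.79 against 8.94 ± 2.31 CPM, adjusted p = 0.0490). Gbp2b, a guanylate-binding protein, had 982 counts in KO and 0 in Mut and was at least 371-fold higher (adjusted p = 0.0455). Malat1, a nuclear noncoding RNA, was higher by 0.70 (log2, SE 0.0462, adjusted p = 0.00267) and Rps9 by 0.82 (SE 0.0900, adjusted p = 0.0490). Jchain was 21.4-fold lower in KO (10.5 ± 1.60 against 225 ± 30.5 CPM, adjusted p = 0.00118). Of 13170 genes, these 8 were called, 7 higher and 1 lower, and 558 had an unadjusted p below 0.05, fewer than the 658 of chance. These numbers rest on a spread shared with the WT libraries, which were the more variable ones. With a spread from only the 2 groups compared, 36 genes were called and 1542 had an unadjusted p below 0.05. The count of genes was 65 and 63 without LSK WT replicate 1 and 2, 3 and 2 without LSK KO replicate 1 and 2, and 4 and 3 without LSK Mut replicate 1 and 2. Lars2 and Rn45s kept their calls without each of the 6 libraries.

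Lists higher in LSK KO than in Mut were ribosomal protein (median log2 0.32, camera adjusted p = 8.76e-12, but 0.531 with an estimated correlation, 1 of 78 over all genes and 16 adjusted over the list alone), lymphoid-primed progenitor (adjusted p = 0.000648, 1 of 21 adjusted over the list alone), oxidative phosphorylation (adjusted p = 0.00147, 0 of 79) and TET partner and chromatin (adjusted p = 0.0455, 0 of 17). Lower were mast cell and basophil (adjusted p = 3.38e-05, 3 of 11 adjusted over the list alone), cell cycle (adjusted p = 5.28e-05, 0 of 36) and granulocyte-monocyte progenitor (adjusted p = 0.00311, 1 of 20 adjusted over the list alone). Of these 7 lists, 0 held with an estimated correlation (adjusted p = 0.344 to 0.652 with an estimated correlation), and 1, the lymphoid-primed list, passed fry. Without KO replicate 1 the oxidative phosphorylation list lost its call, and without KO replicate 2 the granulocyte-monocyte and TET partner lists lost theirs. The same held without Mut replicate 1 for TET partner and oxidative phosphorylation, and without Mut replicate 2 for granulocyte-monocyte and TET partner. With libraries scaled by spike-ins the median moved by -0.59 and 8 genes were called, 4 higher and 4 lower. Lars2, Rn45s and Rplp1 were not among them.

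**Figure D3:**
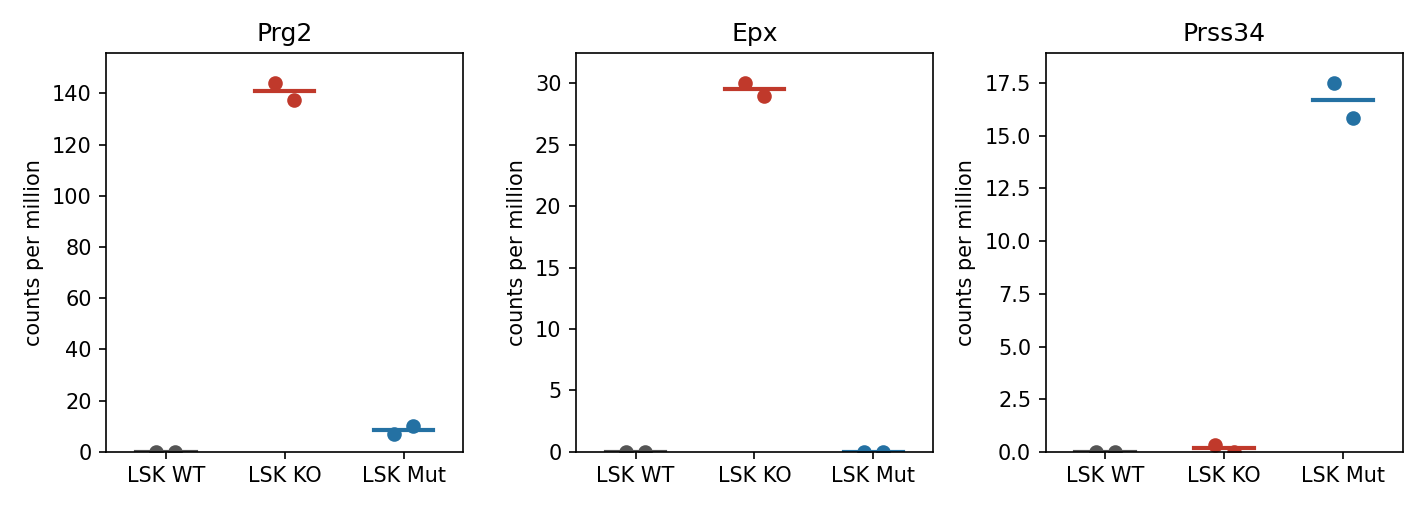
Levels of Prg2, Epx and Prss34 (CPM scaled over all 12 libraries, vertical axes from 0) in the LSK libraries, with points for libraries and bars for group means. Prg2 (144 and 137 CPM) and Epx (30.1 and 28.9 CPM) are high in both LSK KO libraries, and Prss34 (17.5 and 15.8 CPM) in both LSK Mut libraries.

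Within LSK, 4 genes were called for KO and for Mut against WT, all in the same direction: Prg2 and Mpo higher, Rn45s and Lars2 lower. An overlap of 0.0402 genes would arise from independent calls, and simulations in which only the WT libraries were shared gave 0.1 on average and 1 at most. Across genes, which are not independent replicates, the KO and Mut differences correlated at r = 0.834 (Spearman's rho 0.798), where the shared WT libraries alone gave r = 0.831. The covariance of the 2 sets of differences was 3.02, against a mean of 1.52 (1.43 to 1.58) from shared libraries. The simulations leave out spread particular to single genes, which shared WT libraries would pass to both comparisons, so they may understate overlap and covariance. WT libraries were the more variable ones (chi-square per degree of freedom between replicates 83.2, against 24.9 in KO and 32.7 in Mut). The WT libraries were not split between the comparisons, which would leave 1 for each, so part of the overlap may rest on the shared controls. Genes that separated KO from WT and from Mut were Prg2 and Jchain. Those that separated Mut from WT and from KO were Gbp2b, Lars2, Malat1, Rn45s, Rplp1 and Rps9.

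MPP KO against WT compares the libraries labelled KO with WT in MPP, with the reservation that Tet2 counts were not lower in the libraries labelled MPP KO. Erythroblast and megakaryocyte-erythroid lists were higher and granulocyte-monocyte and basophil lists lower. The erythroblast list rose (median log2 1.27, camera adjusted p = 1.85e-23, but 0.054 with an estimated correlation), with 3 of 8 members higher over all genes and 5 adjusted over the list alone. Slc4a1 (chromosome 11, 102348824 to 102366203), the anion exchanger of red cells, was 3.57-fold higher (212 ± 22.1 against 59.4 ± 4.59 CPM, adjusted p = 0.00298), and Alas2, which starts erythroid heme synthesis, 4.32-fold (adjusted p = 0.0216). The megakaryocyte-erythroid progenitor list rose too (adjusted p = 6.97e-06, but 0.104 with an estimated correlation), with Aqp1 2.47-fold, Car2 1.65-fold, Klf1 1.63-fold and Car1 1.44-fold higher, and 8 of 20 members higher and 3 lower adjusted over the list alone. The granulocyte-monocyte progenitor list fell (adjusted p = 7.74e-12, but 0.059 with an estimated correlation), with Elane 1.42-fold and Mpo 1.24-fold lower and 13 of 20 members lower adjusted over the list alone. The mast cell and basophil list fell (adjusted p = 6.65e-14, but 0.0771 with an estimated correlation), with Fcer1a, a chain of the IgE receptor, 1.75-fold and the proteases Prss34 1.69-fold and Mcpt8 1.49-fold lower, and 8 of 12 members lower adjusted over the list alone.

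Among single genes of MPP KO against WT, Alox15, a lipoxygenase, was 3.94-fold higher (232 ± 5.37 against 58.7 ± 5.64 CPM, adjusted p = 0.00269), and Jchain 7.38-fold lower (10.1 ± 2.16 against 74.5 ± 5.22 CPM, adjusted p = 0.00232). Lyz2, lysozyme, was 2.01-fold lower (469 ± 8.01 against 942 ± 9.77 CPM, adjusted p = 0.00182). Thbs1, thrombospondin, rose from 5 to 460 counts (83.7-fold, adjusted p = 0.0283), Inppl1 9.80-fold, Tnfrsf14 6.88-fold, Lpin1 from 12.4 ± 0.384 to 49.6 ± 9.25 CPM and the membrane skeleton protein Add2 3.14-fold. Naip5, a sensor of bacterial flagellin, fell 7.88-fold, the adhesion molecule Vcam1 2.77-fold, Eno1b 2.29-fold, Pglyrp1 1.86-fold and the fatty acid synthase Fasn 1.79-fold, with adjusted p from 0.0117 to 0.0460.

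Cell cycle (adjusted p = 3.17e-06, with Rrm2 1.52-fold higher, 3 of 36 adjusted over the list alone), immediate early (adjusted p = 0.00146, with the heat shock genes Hspa1a 2.22-fold and Hspa1b 2.04-fold higher, 2 of 23), ribosomal protein (adjusted p = 0.00211, 0 of 78) and replication-dependent histone (adjusted p = 0.0269, 0 of 56) were higher as lists in MPP KO than in WT. The immediate early genes Fos, Egr1 and Klf6, called for MPP Mut against WT, differed by only 0.04, 0.08 and 0.03 (log2) between MPP KO and WT. Lymphoid-primed progenitor (adjusted p = 0.00788, 1 of 20 adjusted over the list alone) and Hox and Meis (adjusted p = 0.0368, 0 of 9) were lower. Of these 10 lists, 0 held with an estimated correlation. The adjusted p with an estimated correlation was 0.0771 for cell cycle, 0.128 for immediate early and 0.174 for lymphoid-primed, and between 0.358 and 0.46 for ribosomal protein, histone and Hox and Meis. By fry, 6 of the 10 passed, and the immediate early, Hox and Meis, ribosomal protein and histone lists did not. In all, 47 of 12947 genes were called, 28 higher and 19 lower, with 1097 at an unadjusted p below 0.05 and 647 by chance. The count was 22 and 19 without MPP WT replicate 1 and 2, and 13 and 10 without MPP KO replicate 1 and 2. Alox15, Slc4a1, Jchain and Lyz2 kept their calls without each of the 6 libraries. Among the lists, immediate early and Hox and Meis lost theirs without MPP WT replicate 2, ribosomal protein without MPP WT replicate 1, and histone without MPP WT replicate 1 or MPP KO replicate 2. A spread shared over all 12 libraries gave 15 genes, without Alox15, Slc4a1 and others named above, and spike-in scaling, which moved the median by 0.05, gave 15 (12 higher, 3 lower).

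MPP Mut against WT compares the libraries labelled Mut with WT in MPP. Epx, Prg2 and the granulocyte-monocyte list were lower, and the erythroblast and immediate early lists higher. Epx (chromosome 11, 87864000 to 87875536), eosinophil peroxidase, was 2.52-fold lower (574 ± 2.64 against 1444 ± 42.2 CPM, adjusted p = 0.000283) and Prg2 2.31-fold lower (3010 ± 200 against 6944 ± 492 CPM, adjusted p = 0.000346). The neutrophil list fell (median log2 -0.50, camera adjusted p = 1.59e-10, but 0.0735 with an estimated correlation), with Camp, cathelicidin, 6.84-fold and the calprotectin subunits S100a9 2.14-fold and S100a8 1.95-fold lower, and 5 of 15 members lower and 1 higher adjusted over the list alone. The granulocyte-monocyte progenitor list fell (adjusted p = 1.49e-13), with Elane 1.62-fold, Prtn3 1.61-fold and Mpo 1.13-fold lower and 14 of 20 members lower adjusted over the list alone. Unlike in KO, the mast cell and basophil list rose (adjusted p = 1.28e-07, but 0.0947 with an estimated correlation), with Fcer1a 1.67-fold, Mcpt8 1.52-fold and Prss34 1.40-fold higher and 5 of 12 members higher adjusted over the list alone. Immediate early genes rose (adjusted p = 3.34e-11), with Klf6 1.97-fold, Egr1 1.92-fold and Fos 1.39-fold higher and 10 of 23 members higher adjusted over the list alone. The erythroblast list rose (adjusted p = 2.33e-12), with Slc4a1 2.64-fold higher (157 ± 18.2 against 59.4 ± 4.59 CPM, adjusted p = 0.0116) and 4 of 8 members higher adjusted over the list alone.

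Other lists called for MPP Mut against WT were HSC (higher, adjusted p = 0.00118, 2 of 22 adjusted over the list alone), megakaryocyte-erythroid progenitor (higher, adjusted p = 0.000135, with Tfrc 1.89-fold and Car2 1.34-fold, 4 of 20), inflammatory cytokine and NF-kB (higher, adjusted p = 8.61e-06, 6 of 23) and T and NK cell (lower, adjusted p = 2.44e-06, with Gzma, granzyme A, 15.9-fold lower, 5 of 14). The granulocyte-monocyte, erythroblast and immediate early lists held with an estimated correlation (adjusted p = 0.048 with an estimated correlation in each), and the other 6 did not (0.0735 to 0.0947). All 9 passed fry in the same direction. By gene, Gas5, a noncoding RNA, rose 2.86-fold (609 ± 51.2 against 213 ± 15.2 CPM, adjusted p = 0.00151), Tnfrsf14 5.44-fold, Scin 2.60-fold, Alox15 2.47-fold, the chaperone Hspa8 2.09-fold and Rgs1 1.93-fold. Haptoglobin, Hp, fell 2.14-fold (adjusted p = 0.00268) and Kdelr2 2.06-fold (adjusted p = 0.0307). In all, 29 genes were called, 17 higher and 12 lower, with 1262 at an unadjusted p below 0.05 and 647 by chance. Without MPP Mut replicate 1 or 2 the count was 15 or 19, and Epx, Prg2, Gas5, Camp, Gzma, Hp, S100a8 and S100a9 kept their calls without each of the 6 libraries, as did all 9 lists. With spike-in scaling the median moved by -0.59 and 2297 genes were called, 0.697% of them higher. A spread shared over all 12 libraries gave 13 genes, without Camp, Gzma, Hp, S100a8, S100a9 and Slc4a1.

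MPP KO against Mut gave its lowest camera p in the mast cell and basophil list. This list was lower in KO (median log2 -1.13, camera adjusted p = 9.97e-37, but 0.0721 with an estimated correlation), with 5 of 12 members lower over all genes and 8 adjusted over the list alone. Prss34 (chromosome 17, 25298394 to 25300165) was 2.36-fold lower (2918 ± 173 against 6893 ± 236 CPM, adjusted p = 6.52e-05), Mcpt8 2.26-fold, Fcer1a 2.91-fold and Cpa3, a mast cell carboxypeptidase, 1.84-fold. The neutrophil list was higher in KO (adjusted p = 2.6e-13, but 0.114 with an estimated correlation), with Camp 5.50-fold, Chil3 4.31-fold, S100a9 2.49-fold and S100a8 1.99-fold higher and 5 of 15 members higher adjusted over the list alone. Jchain was 16.0-fold lower (10.1 ± 2.16 against 162 ± 5.94 CPM, adjusted p = 0.000234), Naip5 13.1-fold lower (adjusted p = 0.0158) and Csf2rb2 3.23-fold lower (adjusted p = 0.0449). Gzma was 11.8-fold higher (adjusted p = 0.0336) and Neat1, a nuclear noncoding RNA, 2.43-fold higher (adjusted p = 0.0136).

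Further lists called for MPP KO against Mut were erythroblast (higher, adjusted p = 0.017, 0 of 8), T and NK cell (higher, adjusted p = 0.00516, 2 of 14 adjusted over the list alone), cell cycle (higher, adjusted p = 0.00516, 3 of 36), oxidative phosphorylation (higher, adjusted p = 0.00463, 0 of 79), lymphoid-primed progenitor (lower, adjusted p = 0.0315, 2 of 20), inflammatory cytokine and NF-kB (lower, adjusted p = 0.0317, with Ccl3 1.95-fold lower, 6 of 23) and immediate early (lower, adjusted p = 0.00477, with Klf6 1.93-fold, Egr1 1.81-fold and Fos 1.35-fold lower, 5 lower and 2 higher of 23). With an estimated correlation 0 of the 9 lists held (adjusted p = 0.224 to 0.567 for these 7). By fry, 4 of the 9 passed in the same direction, and the erythroblast, T and NK, immediate early, cell cycle and oxidative phosphorylation lists did not. In all, 31 genes were called, 11 higher and 20 lower, with 1228 at an unadjusted p below 0.05 and 647 by chance. The count was 10 and 12 without MPP KO replicate 1 and 2 and again 10 and 12 without MPP Mut replicate 1 and 2, and Prss34, Fcer1a, S100a9 and Jchain kept their calls without each of the 6 libraries. Both the basophil and the neutrophil lists kept theirs too. The inflammatory list lost its call without any library, and the other 6 lost theirs without at least 1 of the MPP KO and MPP Mut libraries. A spread shared over all 12 libraries gave 14 genes, without Camp, Chil3, Gzma, Neat1, Naip5, Csf2rb2, Fcer1a and S100a9. Under spike-in scaling the median moved by 0.65 and 3254 genes were called, 99.4% of them higher.

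**Figure D4:**
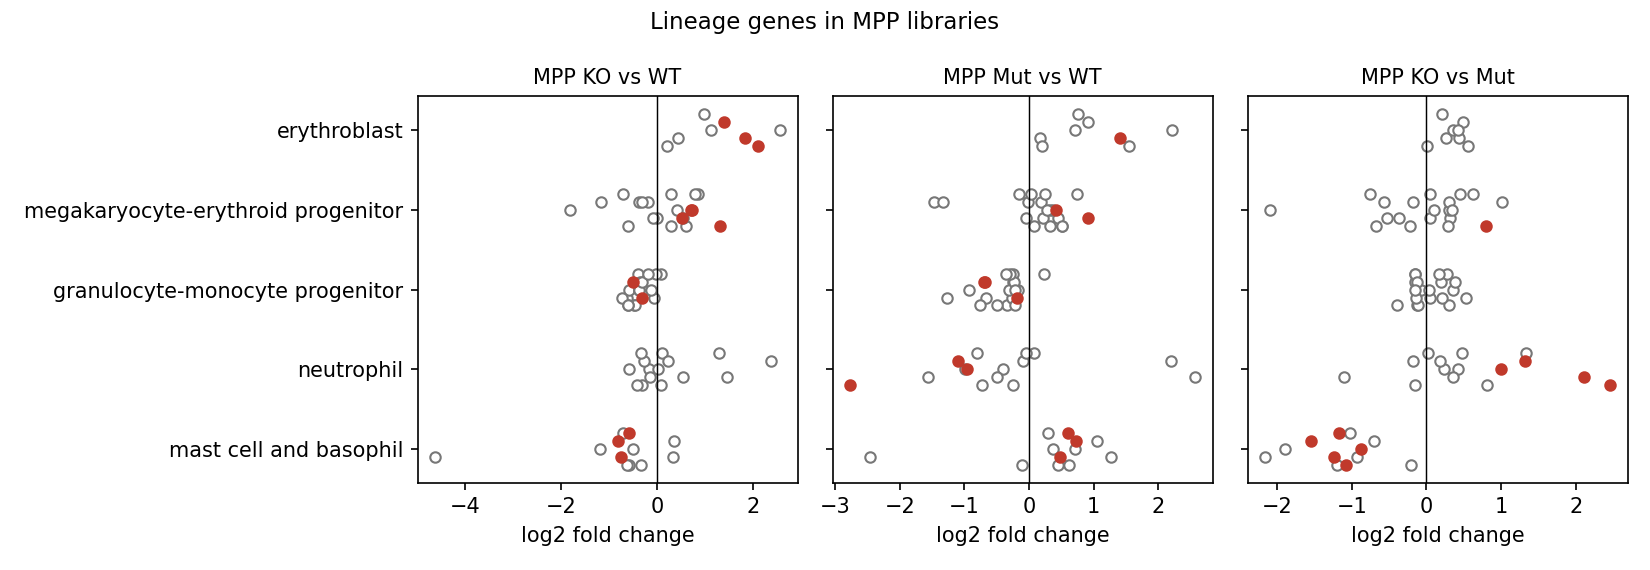
Log2 fold changes (horizontal axes) of the measured members of lineage lists in the MPP comparisons, where filled points are past an adjusted p of 0.05 over all genes. The mast cell and basophil genes Prss34, Mcpt8 and Fcer1a lie below 0 for KO against WT (-0.76, -0.58 and -0.81) and above 0 for Mut against WT (0.48, 0.60 and 0.74).

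Within MPP, 10 genes were called for KO and for Mut against WT in the same direction (Alox15, Car2, Gas5, Slc4a1 and Tnfrsf14 higher, Elane, Epx, Hp, Mpo and Prg2 lower), and 4 in opposite directions, the basophil genes Prss34, Mcpt8 and Fcer1a and the gene Lars2. Independent calls would share 0.0544 genes, and simulations with shared WT libraries gave 0. The differences correlated across genes at r = 0.471 (rho 0.419), against 0.444 from the shared libraries alone. Their covariance was 0.777, against a mean of 0.367 (0.340 to 0.404) from shared libraries, an excess of 0.410. As in LSK, the simulations leave out spread particular to single genes, so the excess alone does not show a shared effect. KO differed from both WT and Mut in 11 genes, among them Jchain, Naip5, Aqp1, Lyz2 and Prss34, and Mut from both WT and KO in 15, among them Camp, Gzma, Epx, Prg2, S100a8, S100a9 and Egr1.

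The interactions ask whether a genotype effect differed between LSK and MPP. They share a spread over all 12 libraries, which joins the more variable LSK WT libraries with less variable ones. P values of the interactions against WT may therefore be too small. For KO against WT, Prg2 was at 141 ± 4.81 CPM in LSK KO and had 2 counts in LSK WT, while in MPP it was lower in KO (4729 ± 287 against 7324 ± 569 CPM, interaction adjusted p = 9.05e-08). Epx was at 29.5 ± 0.785 CPM in LSK KO with 0 counts in LSK WT, and at 1023 ± 43.5 against 1522 ± 55.0 CPM in MPP (adjusted p = 2.63e-07). The granulocyte-monocyte progenitor list was higher in LSK relative to MPP (camera adjusted p = 2.77e-13, but 0.0687 with an estimated correlation), with Mpo, Irf8, Igsf6 and Ly6c2 among 7 members past the threshold of 20, and 11 adjusted over the list alone. Immediate early genes were relatively lower in LSK (adjusted p = 7.04e-10, with Nr4a1 past the threshold, 7 of 24 adjusted over the list alone). T and NK cell genes were relatively higher (adjusted p = 2.77e-07, with Nkg7 and Ncr1, 7 of 14 adjusted over the list alone). Dendritic cell and MHC class II (adjusted p = 0.000623), glycolysis (adjusted p = 0.00735) and interferon response (adjusted p = 0.046) were relatively higher, and ribosomal protein (adjusted p = 2.77e-07), megakaryocyte-erythroid progenitor (adjusted p = 0.000623) and replication-dependent histone (adjusted p = 0.0341) relatively lower. With an estimated correlation the T and NK (adjusted p = 0.018) and immediate early lists (adjusted p = 0.0102) held, and the other 7 did not (0.0687 to 0.318). By fry, 6 of the 9 passed, without the megakaryocyte-erythroid, ribosomal protein and histone lists. Other genes named were Arhgef11, Polh and Cxcr3 (relatively higher, each with 0 counts in LSK WT), and Tbrg3 and Sstr2 (relatively lower, each with 0 counts in MPP WT). In all, 102 of 14033 genes were called, 80 higher and 22 lower, with 1734 at an unadjusted p below 0.05 and 702 by chance. Without replicate 1 or 2 of a group the count was 813 or 903 (LSK WT), 12 or 24 (LSK KO), 50 or 48 (LSK Mut), 7 or 6 (MPP WT), 4 in each case (MPP KO) and 20 or 35 (MPP Mut), while Epx and Prg2 kept their calls throughout. The megakaryocyte-erythroid, dendritic, interferon and histone lists lost their calls without at least 1 LSK WT library.

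For Mut against WT, 355 genes were called in the interaction, 213 higher and 142 lower (2390 at an unadjusted p below 0.05, 702 by chance). Prss34 had 606 counts in LSK Mut and 0 in LSK WT, and rose in MPP from 5204 ± 251 to 7279 ± 257 CPM (interaction adjusted p = 8.71e-05). Mecom, a transcription factor of stem cells, was at 25.9 ± 9.17 CPM in LSK Mut and 58.0 ± 5.51 in LSK WT, and had 74 counts in MPP Mut and 1 in MPP WT (adjusted p = 0.0242). Syt3, Arhgef11, Mapk13 and Cd14 had 0 counts in LSK WT, and Sdc3, Tbrg3 and Sstr2 had 0 in MPP WT, with Col16a1 at 3 counts there. The granulocyte-monocyte progenitor list was relatively higher in LSK (camera adjusted p = 9.1e-20, 9 of 20 members, with Mpo 3.22-fold and Elane 5.07-fold), and the immediate early list relatively lower (adjusted p = 8.15e-12, 6 of 24, with Fosb 2.94-fold and Egr1 2.52-fold). Ribosomal protein genes were relatively lower (adjusted p = 6.85e-13, but 0.165 with an estimated correlation, 15 of 78 over all genes, 25 lower and 2 higher adjusted over the list alone), as were HSC (adjusted p = 0.00771, 2 of 24), megakaryocyte-erythroid progenitor (adjusted p = 0.00159, with Car1 and Tfrc) and TET partner and chromatin genes (adjusted p = 0.0208, with Kmt2a 4.29-fold). Relatively higher were T and NK cell (adjusted p = 0.000413), glycolysis (adjusted p = 0.00174), dendritic cell and MHC class II (adjusted p = 0.00174), cell cycle (adjusted p = 0.0208) and mast cell and basophil (adjusted p = 0.0471), the last lost without any of the 12 libraries. The granulocyte-monocyte (adjusted p = 0.0353), T and NK (0.0478) and immediate early lists (0.00577) held with an estimated correlation, and the other 8 did not (adjusted p = 0.06 to 0.273 with an estimated correlation). All but mast cell and basophil, 10 of the 11, passed fry. The count of genes without replicate 1 or 2 of a group was 1297 or 1425 (LSK WT), 121 or 108 (LSK Mut), 122 or 94 (MPP WT), 226 or 218 (MPP KO) and 88 or 103 (MPP Mut). Megakaryocyte-erythroid, dendritic and cell cycle lists lost their calls without at least 1 LSK WT library.

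For KO against Mut, 9 genes were called in the interaction, 5 higher and 4 lower (896 at an unadjusted p below 0.05, 702 by chance): Epx, Prg2, Lars2, Rn45s and Rplp1 relatively higher in LSK, and Chil3, Prss34, Tfr2, a transferrin receptor, and Elane relatively lower. Epx, Prg2, Lars2, Rn45s and Prss34 kept their calls without each of the 12 libraries. The count without replicate 1 or 2 of a group was 39 or 34 (LSK WT), 6 or 5 (LSK KO), 7 or 10 (LSK Mut), 8 in each case (MPP WT), 6 in each case (MPP KO) and 5 in each case (MPP Mut). Lists relatively higher in LSK were lymphoid-primed progenitor (adjusted p = 0.00033), ribosomal protein (adjusted p = 0.00092), TET partner and chromatin (adjusted p = 0.0405) and Hox and Meis (adjusted p = 0.0405). Relatively lower were cell cycle (adjusted p = 1.75e-06), neutrophil (adjusted p = 0.000359), granulocyte-monocyte progenitor (adjusted p = 0.00092), replication-dependent histone (adjusted p = 0.0197) and mast cell and basophil (adjusted p = 0.0231). Of these 9 lists 0 held with an estimated correlation (adjusted p = 0.0625 to 0.542 with an estimated correlation), and 4 passed fry: lymphoid-primed, TET partner, cell cycle and neutrophil. Among these, mast cell and basophil kept its call only without LSK Mut replicate 2, and the Hox and Meis list lost its call without 7 of the 12 libraries. Without LSK KO replicate 2 the granulocyte-monocyte, TET partner and histone lists lost theirs as well. Across the 3 interactions (KO against WT, Mut against WT, KO against Mut), spike-in scaling moved the medians by 0.51, 1.74 and -1.23 and gave 2, 5428 and 9 genes, of which 100%, 99.7% and 11.1% were higher.

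LSK against MPP in WT served as a reference for the sorted fractions. MPP is a label here and not a cell type read from markers, as Mpo was at 37456 ± 952 CPM, Elane at 12675 ± 521 and Prss34 at 5204 ± 251 in MPP WT. Stem cell genes were higher in LSK, and granulocyte-monocyte, T and NK cell and basophil genes higher in MPP. The HSC list was higher in LSK (camera adjusted p = 7.83e-11), with 14 of 24 members higher over all genes and 16 adjusted over the list alone, among them Hlf (26.8-fold). Hox and Meis genes were higher (adjusted p = 8.22e-05, but 0.0553 with an estimated correlation, with Meis1 6.44-fold and Hoxa9 9.27-fold, 6 of 17 adjusted over the list alone). Granulocyte-monocyte progenitor genes were lower in LSK (adjusted p = 2.36e-54, 16 of 20 members, with Elane 85.0-fold and Mpo 23.7-fold), as were neutrophil (adjusted p = 1.13e-06, 11 lower and 1 higher of 15), T and NK cell (adjusted p = 5.23e-10, 11 of 14, with Nkg7 5.33-fold), mast cell and basophil (adjusted p = 2.12e-20, 7 of 12, with Mcpt8 156-fold) and cell cycle genes (adjusted p = 1.19e-08, 23 lower and 2 higher of 36, with Rrm2 7.21-fold). Prss34 and Epx had 0 counts in LSK WT and were at least 37930-fold and 11114-fold higher in MPP WT, and Prg2 had 2 counts against 181108. Prg3 and Fcnb, also with 0 counts in LSK WT, were at least 2478-fold and 875-fold higher in MPP WT. Vdr, Insrr, Sdc3, Map9 and Ndn had 0 counts in MPP WT. By the counts of both libraries, they were at least 327-fold, 246-fold, 180-fold, 166-fold and 165-fold higher in LSK WT. Their LSK WT libraries differed widely, at 36.1 ± 31.6, 28.1 ± 14.5, 19.7 ± 18.9, 18.6 ± 13.5 and 17.6 ± 21.4 CPM in the same order. The folds of these genes are thus bounds for counting error in the group and not for the spread between its libraries. Tet2 and Tet1 were higher in LSK WT by 1.12 (log2, SE 0.286, adjusted p = 0.0158) and 1.85 (SE 0.445, adjusted p = 0.0115), and Tet3 by 0.63 (SE 0.299, adjusted p = 0.153), which missed the threshold.

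Further lists differed between LSK and MPP in WT. Glycolysis (adjusted p = 0.000118), oxidative phosphorylation (adjusted p = 0.000906) and megakaryocyte-erythroid progenitor (adjusted p = 0.0277) were lower in LSK. Ribosomal protein (adjusted p = 3.51e-10), immediate early (adjusted p = 0.000409), interferon response (adjusted p = 0.0205), TET partner and chromatin (adjusted p = 0.0277) and lymphoid-primed progenitor (adjusted p = 0.0198) were higher. HSC, granulocyte-monocyte, neutrophil, T and NK, mast cell and basophil, immediate early, cell cycle and glycolysis held with an estimated correlation (adjusted p = 0.00323 to 0.027 with an estimated correlation), and the other 7 did not (0.0553 to 0.416). All 15 passed fry, but so did most lists here (24 of the 27 tested), so passing adds little to these calls. The lymphoid-primed list had Flt3 9.77-fold and Dntt 5.60-fold higher, yet a median of -0.08 and a mean of -0.24 (log2), opposite in sign to its test, and its call was lost without any of the 12 libraries. The megakaryocyte-erythroid list kept its call without 3 of them. In all, 3361 genes were called, 1438 higher and 1923 lower (5206 at an unadjusted p below 0.05, 702 by chance). The count was 2186 and 2018 without MPP WT replicate 1 and 2. Spike-in scaling moved the median by 4.17 and gave 11550 calls, 99.0% of them higher in LSK, a shift common to all genes.

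B cell, stroma and endothelium, cell cycle inhibitor, p53 target, Tet2 neighbour and 129-B6 passenger lists were not called in any of the 6 genotype comparisons. The lowest adjusted p was 0.15 for B cell, 0.109 for stroma and endothelium, 0.244 for cell cycle inhibitor, 0.317 for p53 target, 0.0869 for Tet2 neighbour and 0.154 for 129-B6 passenger. Of the sex-linked list, the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d had counts in all 12 libraries, and Xist had at most 27 counts in a library.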

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

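The tests in this part were chosen after the results were seen, except the interactions and the test of transcript length, which were set before.

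The interactions share a spread over all 12 libraries, although the LSK WT libraries were the more variable ones. Within LSK that spread raised the calls from 6 to 272 for KO and from 168 to 949 for Mut against WT. In MPP it lowered them from 47 to 15 and from 29 to 13. The p values of the interactions against WT may thus be too small. With this limit, the test of the difference itself called 102 genes for KO against WT, 355 for Mut against WT and 9 for KO against Mut. Without LSK WT replicate 1 or 2 these counts were 813 or 903, 1297 or 1425, and 39 or 34, and without MPP KO replicate 1 or 2 the count for KO against WT was 4 in each case. For KO against WT, the difference (log2, effect in LSK minus effect in MPP) was -4.44 for Nxpe2 (SE 0.648, adjusted p = 0.0230), -3.31 for Gzmb (SE 0.647, adjusted p = 0.0477) and -2.77 for Nedd9 (SE 0.528, adjusted p = 0.0440), calls kept in 6, 2 and 2 of the 12 fits that each left out a library, and lost for Gzmb and Nedd9 with the replicate block. For KO against Mut it was 3.47 for Prg2, 2.50 for Lars2, 1.32 for Rn45s and 1.01 for Rplp1, and -6.13 for Chil3, -5.18 for Prss34, -1.63 for Tfr2 and -1.55 for Elane, where Prg2, Lars2, Rn45s and Prss34 kept their calls without each of the 12 libraries, and Rplp1, Chil3, Tfr2 and Elane kept theirs in 3, 3, 4 and 9 of these fits. The spike-in ERCC-00130 enters the comparisons of genes only through the total used in spike-in scaling. It took 17.2% ± 0.529 of spike-in counts in MPP WT and 18.6% ± 3.20 in LSK WT, against 2.67% to 3.75% in the KO and Mut groups.

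Prg2 and Epx were at 141 ± 4.81 and 29.5 ± 0.785 CPM in LSK KO, with 2 and 0 counts in LSK WT. Reads carried over from the MPP KO libraries would bring their other abundant transcripts at the same share (3.05% and 2.91% by Prg2), yet Prss34, with 0 counts in LSK WT, had 6 and 0 counts in the LSK KO libraries, at most 0.352% of the level needed. S100a8, already at 62.8 CPM in LSK WT, was at 34.8% and 19.3% of that level. Mcpt8 (64.8% and 39.4%), Elane (70.5% and 66.5%) and S100a9 (94.9% and 98.4%) came nearer to it, but had 13.9, 149 and 53.5 CPM in LSK WT already. Eosinophil-lineage cells among the sorted cells are a candidate source: Epx, Prg3 and Ear1, all 3 of the granule genes tested, stood to Prg2 at 0.969, 0.620 and 2.23 times their MPP KO proportion, though Ear1 had 70 counts in LSK WT, and LSK Mut had 310 counts of Prg2 with 0 of Epx and of Ear1. Open remain eosinophil-lineage cells in the single LSK KO pool and granule gene expression within its LSK cells, with the KO genotype as their origin untested.

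Ribosomal RNA and ribosomal protein counts were lower in LSK Mut than in LSK WT, with a median log2 difference of -0.59 over the ribosomal protein list, whose call was lost with an estimated correlation (adjusted p = 0.34). Transcript length is argued against, since it correlated with the differences of genes outside the list at rho = -0.0599, and 1000 length-matched random lists had a lowest median of -0.28. A few abundant genes taking counts from the others is argued against as well, because the 10 largest, leaving out the list, Rn45s and Lars2, took 4.02% ± 0.104 of counts in LSK WT and 3.82% ± 0.0586 in LSK Mut (SD, n = 2), where 36.1% would be needed, and would move the others by 0.00130 at the lowest (log2). A fault of WT with the same effect on ribosomal protein counts in both populations is argued against by the median of 0.0479 in MPP Mut against WT. This median cannot exclude a shared difference in preparation that acts otherwise in LSK than in MPP. Spike-in proportions did differ between WT and the other genotypes in both populations. A difference in the preparation of the LSK libraries alone cannot be told apart from the genotype, since each genotype's LSK libraries come from a single pool.

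Lineage lists were called between genotypes in the MPP libraries, though the calls of the 3 lists below were lost with an estimated correlation (adjusted p = 0.0721, 0.054 and 0.0735 in their order), and a changed share of mature or committed cells would move the markers of a lineage together. A single common shift was tested over members with a mean of at least 100 counts, by Cochran's Q against a chi-square distribution, approximate with SEs from 2 libraries per group: basophil and mast cell genes in KO against Mut (common log2 -1.11, members -1.89 to -0.21, p = 6.69e-19), erythroblast genes in KO against WT (1.31, 0.22 to 2.57, p = 1.68e-08) and neutrophil genes in Mut against WT (-0.88, -2.77 to 2.58, p = 3.84e-26). Members thus moved unequally, and Ltf rose by 2.58 where a lower share of neutrophils would lower it, though past the threshold only when adjusted over the list alone (0.203 adjusted over all genes). Equal shifts are required only if no other sorted cells express these genes, which was not tested, so the reading was changed, after these p values were seen, from exclusion to undecided for all 3 lists. A changed share of cells and changed expression within cells cannot be told apart with bulk libraries.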

How the results depend on the processing

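The alternative without Rn45s and Lars2 was chosen after the results were seen, and the others before. Among tests of named genes under an alternative or without a library, 1318 had the same direction and side of the threshold, 542 the same direction without passing it, 5 passed it where the result had not, and 6 reversed. Among tests of called lists the numbers were 1165, 286, 0 and 13. Counts of genes moved by more than 1.5 times under most alternatives, and except where stated the cause was not tested.

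DESeq2 gave 593, 1398 and 116 genes for KO against WT, Mut against WT and KO against Mut in LSK, 272, 302 and 288 in MPP, and 580, 1093 and 119 for the interactions. Without a filter on low counts the numbers were 50, 475 and 22, then 189, 217 and 195, then 278, 662 and 42. A test beyond a 1.5-fold change, stricter by construction, gave 3, 19 and 3, then 3, 5 and 8, then 4, 56 and 5, and 1884 for LSK against MPP in WT. Spike-in scaling gave 71 and 3002 for KO and Mut against WT in LSK, 15, 2297 and 3254 in MPP, 2 and 5428 for the first 2 interactions and 11550 for LSK against MPP in WT. A spread shared over all 12 libraries gave 272, 949 and 37 in LSK and 15, 13 and 14 in MPP. A spread from only the 2 groups compared gave 3, 5 and 36 in LSK and 26 and 17 for KO and Mut against WT in MPP. With the replicate number as a block, Mut against WT and KO against Mut in LSK gave 35 and 5, KO and Mut against WT in MPP 23 and 19, and the KO against WT interaction 34. Without Rn45s and Lars2, which were among the genes called, LSK KO against WT and KO against Mut gave 3 each and the KO against Mut interaction 5.

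The classes, named here LSK shared KO and Mut calls, LSK KO-distinct genes and LSK Mut-distinct genes, and likewise for MPP (MPP Mut-distinct genes, for example), numbered 456, 12 and 95 in LSK and 82, 88 and 84 in MPP with DESeq2, and 40, 4, 16, 60, 58 and 52 in the same order without a filter. Beyond a 1.5-fold change they numbered 2, 1, 2, 0, 1 and 2 by edgeR, where MPP KO and Mut against WT had 348 and 445 genes at an unadjusted p below 0.05. With the spread of all 12 libraries they numbered 230, 11, 27, 2, 3 and 8. Spike-in scaling gave 65 shared and 4 KO-distinct genes in LSK and 6 shared and 1755 Mut-distinct genes in MPP. With only the 2 groups compared there were 2 shared and 1 KO-distinct in LSK and 4 and 3 in MPP, and with the replicate block 1 KO-distinct in LSK, 4 shared and 5 KO-distinct in MPP. Without Rn45s and Lars2 LSK had 2 shared, 1 KO-distinct and 2 Mut-distinct genes, and with DESeq2 size factors 1 KO-distinct gene.

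Leaving out a library gave 0 to 1690 genes for LSK KO against WT, 5 to 2631 for LSK Mut against WT, 2 to 65 for LSK KO against Mut, 10 to 41 for MPP KO against WT, 15 to 28 for MPP Mut against WT, 10 to 34 for MPP KO against Mut, and 2018 to 4198 for LSK against MPP in WT. For the interactions the ranges were 4 to 903 for KO against WT, 88 to 1425 for Mut against WT and 5 to 39 for KO against Mut. The LSK shared KO and Mut calls ranged from 0 to 1402, the KO-distinct from 0 to 13 and the Mut-distinct from 2 to 48, and in MPP from 4 to 7, 2 to 9 and 6 to 16. The 0 calls of edgeR for LSK KO against WT came without KO replicate 1 or 2 (698 and 762 genes at an unadjusted p below 0.05).

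Reversals came mostly with spike-in scaling, which moves every gene by the same shift, so these changes of sign say nothing about the single gene. Its log2 values were 0.330 (Tet2, LSK Mut vs WT), -0.409 (Tet2, MPP Mut vs WT), 0.494 (Tet2, MPP KO vs Mut) and -0.258 (Rplp1, interaction KO vs Mut, LSK minus MPP). Leaving out a library gave -0.178 (without MPP WT replicate 2) to 0.248 (without MPP WT replicate 1) for Tet2, MPP KO vs WT, and -0.0247 to 0.402 for Tet2, MPP Mut vs WT, without the same libraries. Lists are tested against all other genes on scores scaled by the spread of each gene. A shift common to all genes need not move these scores equally and may contribute to a reversed list. The cause of the list reversals was not tested. Cell cycle, glycolysis and oxidative phosphorylation in LSK against MPP in WT passed the threshold in the reversed direction. Adjusted p values of lists that reversed under spike-in scaling were 0.896 for TET partner in LSK Mut against WT, 0.394 for oxidative phosphorylation in LSK KO against Mut and 0.450 for immediate early in MPP KO against Mut. In the interactions they were 0.577 (Mut against WT) and 0.456 (KO against Mut) for TET partner, and 0.347 for ribosomal protein and 0.836 for histone (KO against Mut). They were 0.709 for megakaryocyte-erythroid and 0.728 for Hox and Meis in LSK against MPP in WT, 0.000801 in the list cell cycle, LSK vs MPP in WT, 0.0196 in the list glycolysis, LSK vs MPP in WT, and 3.53e-09 in the list oxidative phosphorylation, nuclear, LSK vs MPP in WT. Leaving out a library gave adjusted p from 0.0580 (without LSK Mut replicate 2) to 0.949 (reversed, without LSK WT replicate 2) in the list mast cell and basophil, interaction Mut vs WT, LSK minus MPP.

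Depth limits genes with few counts: a count of 0 in a library leaves up to 0.127 to 0.327 CPM open.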

Other observations

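All tests in this part were chosen after the results were seen. Gbp2b and Zfp429, singled out after their values were seen, were near absent from every Mut library of both populations. Gbp2b (chromosome 3, 142594847 to 142619179) had 0 counts over the 4 Mut libraries and 45 to 507 in each of the other 8, and Zfp429 (chromosome 13, 67387905 to 67399819) had 6 counts over the 4 Mut libraries and 52 to 149 in each of the others.

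Gbp2b lies on the chromosome of Tet2 (133463679 to 133545139), and sequence of the strain in which the locus was targeted, carried along with it, may silence such a gene or alter its mapping. Within 20 Mb of Tet2, 4 of 133 genes (1810037I17Rik, Gbp2b, Ptbp2 and Snx7) were called in a comparison with Mut, where 2.00 were expected (odds ratio 2.05, 95% interval 0.544 to 5.45, Fisher exact p = 0.141). With so few calls expected, linked sequence stays undecided, and Zfp429 lies on another chromosome.

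The spike-ins of the WT libraries may come from another mix than those of the KO and Mut libraries. Across 14 spike-ins with at least 500 counts, the log2 ratios of KO and Mut to WT correlated between the MPP and the LSK libraries at r = 0.872 (rho 0.895), while the median absolute ratio of KO to Mut was 0.02 in MPP and 0.25 in LSK. Of 42 such spike-ins in MPP, 9 lay between -2.23 and -1.84 and the next at -0.68. A different mix, or a different lot, would leave the total of the spike-ins usable only as far as the mixes hold equal amounts, which the labels do not state. Whichever the source, spike-in proportions separated WT from KO and Mut in both populations. The comparisons of KO and of Mut with WT, and the calls they share, thus coincide with a difference in preparation. Such a difference cannot be told apart from the genotype.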
